A study of Danio rerio with 6 samples.

How the data were processed

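Whole kidney marrow, the blood-forming tissue of the adult zebrafish, was profiled by bulk RNA sequencing in 6 libraries, 3 from wild-type fish and 3 from fish heterozygous for a mutation in rad21a. Each library was made from the pooled marrow of 3 adult fish, per the labels. Total RNA was extracted with a NucleoSpin column kit and libraries were made with the Illumina TruSeq RNA kit, version 2, per the labels' protocols. Per the submitters' processing notes, FastQC, HISAT2 2.0.4 and featureCounts were used with genome build GRCz11. The deposited values are TPM, transcript abundances scaled to a fixed total per library, one table for all 6 libraries, with 32057 Ensembl gene identifiers. The gene annotation, the gene lengths behind the TPM, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads from overlapping or antisense genes may therefore be mixed in a gene's value, and genes with near-identical copies are uncertain.

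TPM sums to 1e+06 in every library and keeps no read depth, so no total read count is known and no counting interval was computed. Ratios between libraries of the lowest values in the table gave relative depths of 0.805 and 1.06 for wild-type pools 2 and 3 and of 1.03, 1.34 and 0.963 for heterozygous pools 1 to 3, with wild-type pool 1 set to 1. Whole reads were not recovered from these values, so no count test was run. Since the sum is fixed, a transcript class that takes a large share of a library lowers all others in it. Globin genes held 22.2%, 6.18% and 12.5% of the TPM in the wild-type pools and 8.15%, 18.8% and 12.2% in the heterozygous pools.

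Symbols came from a table of gene names, in which 28988 of the 32057 identifiers had one. That table gives many zebrafish copies the same human-style symbol in capitals, so genes with a shared symbol are named with their identifier. No gene positions on the build of the files were used, and no coordinates are given. The planned test of whether called genes gathered on the chromosome of rad21a was not run for that reason.

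The comparison used limma 3.58.1 in R 4.3.3 on log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 16537. A linear model with genotype as the only term was fitted, the variances were moderated with a mean trend, p-values were two-sided and adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was the threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The values of single cohesin genes were also compared by a two-sided exact permutation test over the 20 arrangements of 3 against 3, whose smallest p is 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, over the lists with at least 4 tested members, with p-values adjusted over those lists. Beside it stood camera with a correlation estimated for each list, and fry, which asks whether a list's genes move on balance in 1 direction.

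The groups, the test, the alternatives, 36 gene lists and the rule for naming genes were fixed before the data were examined. A list member matched by its exact symbol, and 34 lists had enough tested members. The list of core cohesin subunits did not, because the name table gives most copies without their suffix, and it was tested only with members matched without the suffix. No symbol of the gimap list was found. The rule named the cohesin subunits, then up to 12 genes per direction with the largest called change, with a gene-like symbol and with no overlap between the groups, up to 4 members per list with the smallest p, and the 2 genes without a gene-like symbol that had the smallest p. Genes outside the rule are said to have been chosen after their values were seen. Some list members that the rule names are not reported here.

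Alternatives covered the pseudocount, the filter, rescaling by median ratios, quantile normalization, removal of globin and mitochondrial genes, the variance trend, weights per library, replicate number as a block, a looser threshold, a minimum fold change, camera on ranks, and leaving out each library in turn. Chosen after seeing the data were a fit without wild-type pools 2 and 3, a fit with a germ cell score (the mean of the gonad list) as a covariate and list matching without copy suffixes. The fit without wild-type pools 2 and 3 leaves 1 wild-type library, which is assumed to vary like the heterozygous pools, so its p-values rest on the spread of those alone. The steps were tested on simulated data with the mean levels of the 16537 tested genes and spreads drawn from the fitted variance trend. The 200 changed genes were drawn from those with a mean log2(TPM + 1) above 2, so recovery of lower genes is not known. Of genes changed by 1 on the log2 scale, 2% were recovered, and of genes changed by 3, 78% were recovered, with 2 false calls among 82. A planted list was called by camera with an adjusted p of 9.7e-28 and an unplanted one had 0.30. Simulated genes varied independently, so this cannot show how often camera calls unchanged lists whose genes vary together. Limma p-values of single genes measure the spread between pools of 3 fish. Camera p-values at the preset correlation do so only in part, since they take the genes of a list as nearly independent. Correlations estimated for the called lists ran from 0.22 to 0.76.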

Results

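The data compared gene expression in the whole kidney marrow of adult zebrafish that were wild type or heterozygous for the nz171 allele of rad21a, a nonsense mutation in exon 8. Rad21 is the subunit that closes the ring of cohesin, the complex that holds sister chromatids together and shapes chromatin loops. Wild-type fish were siblings from crosses between heterozygous parents, per the series' design text. Whether the pools shared a clutch, and the sex of the pooled fish, are not given in the sources used here. Each genotype had 3 libraries, each from a pool of 3 fish, named here as wild-type pools 1 to 3 and heterozygous pools 1 to 3. Between 25643 and 26455 genes had a TPM above 0 in a library, and read depth is unknown because TPM does not keep it.

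The libraries did not differ by genotype alone. The 12 tested genes of the gonad list other than STAR, most of them egg genes, summed to 15790 and 4410 TPM in wild-type pools 2 and 3, against 268.4 TPM in wild-type pool 1 and 191.7, 137.4 and 8.26 TPM in heterozygous pools 1 to 3. The first principal component held 61.9% of the variance and placed wild-type pools 2 and 3 at 112 and 53.4, wild-type pool 1 at -19.0 and the heterozygous pools between -66.7 and -36.1. Pearson correlations across genes ranged from 0.815 to 0.937 within the wild type, from 0.938 to 0.968 within the heterozygotes and from 0.744 to 0.923 between genotypes. Genes of the steroid-making interrenal tissue, which lies within the fish kidney, summed to 438.5 and 712.1 TPM in heterozygous pools 2 and 3 and to between 6.86 and 13.3 TPM in the other libraries.

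The mutated gene was examined first. The level of rad21a was 97.4 ± 20.3 TPM in the wild type and 63.6 ± 3.22 TPM in the heterozygotes (SD, n = 3 each), 65.3% of the wild-type mean, and all 3 heterozygous pools lay below all 3 wild-type pools. The log2 fold change was -0.58 with a standard error of 0.22 and a 95% interval from -1.12 to -0.05. That difference did not pass the threshold over all genes (limma adjusted p = 0.30, unadjusted limma p = 0.036), and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. A gene named RAD21 in the name table (ENSDARG00000035655) stood at 1.45 ± 0.498 TPM in the wild type and 1.48 ± 0.227 TPM in the heterozygotes. SMC3, an ATPase arm of the ring, stood at 21.1 ± 4.11 and 24.1 ± 1.72 TPM, and SMC1A (ENSDARG00000058203), the other arm, at 25.01 ± 1.69 and 26.6 ± 2.32 TPM. Among the genes named STAG1 and STAG2, accessory subunits that bind the ring, log2 fold changes ran from 0.17 to 0.42. The largest was that of STAG1 (ENSDARG00000061205), at 1.55 ± 0.222 TPM in the wild type and 2.41 ± 0.297 TPM in the heterozygotes (limma adjusted p = 0.34). No tested core cohesin subunit passed the threshold over all genes, and none did with p adjusted over the list alone. Core subunits as a list, matched without copy suffixes, were not called either (limma camera adjusted p = 0.39). With weights per library, a fit that did not converge, rad21a passed the threshold (log2 fold change -0.78, limma adjusted p = 0.0011). Signs of the fold changes of STAG2 (ENSDARG00000011783), SMC3, SMC1A and RAD21 turned under some alternatives.

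**Figure D1:**
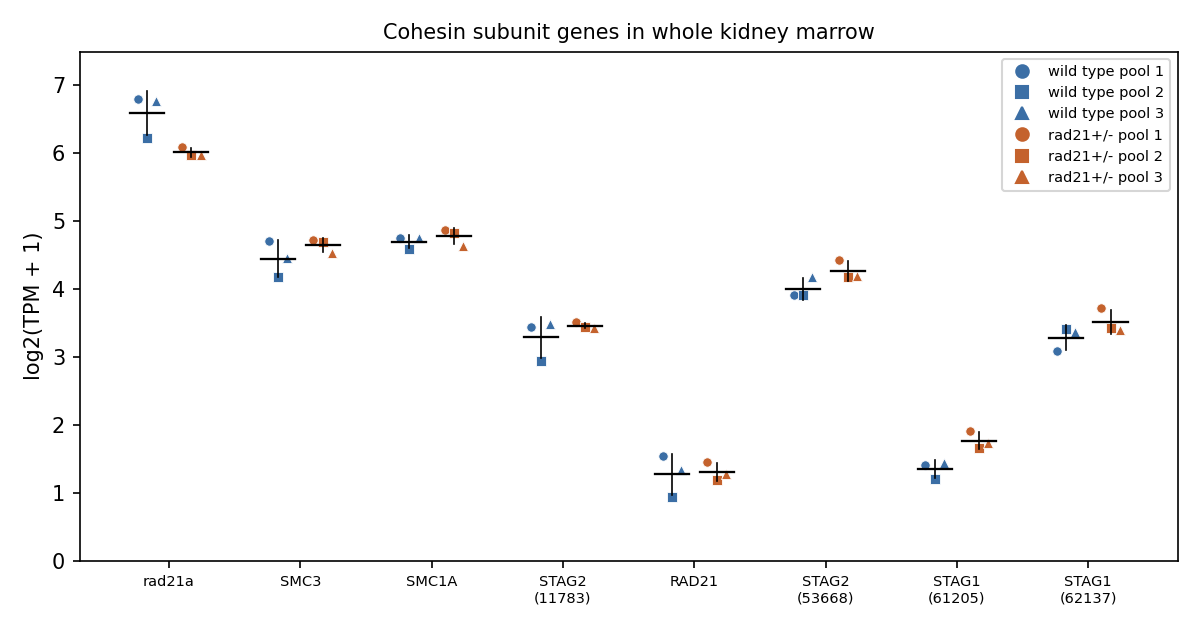
Expression of the tested cohesin subunit genes as log2(TPM + 1), 1 point per library, with horizontal bars for the mean and vertical bars for the SD of 3 pools, and the last digits of the identifier under shared symbols. For rad21a, the heterozygous pools (61.6 to 67.3 TPM) lie below the wild-type pools (73.9 to 110.1 TPM).

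Across all tested genes, called genes with the largest differences were near 0 in every pool of a genotype or many-fold apart. mfap4.6, of a family of secreted fibrinogen-domain proteins used as macrophage markers in zebrafish, rose from 32.6 ± 10.2 to 652 ± 221 TPM (SD, n = 3 each), a 19.98-fold difference. The MHC class II genes mhc2dga and mhc2dhb rose, to 49.6 ± 29.5 and 36.3 ± 15.1 TPM, from at most 0.0332 TPM in any wild-type pool for the former and from 1.59 ± 1.003 TPM for the latter. The list of MHC class II antigen presentation genes fixed in advance, to which neither belongs, was not called (limma camera adjusted p = 0.79). Among the lower genes, ly6m5 and ly6m2, of the Ly6 family of small surface proteins, stood at 68.1 ± 44.4 and 33.9 ± 24.0 TPM in the wild type and at no more than 0.155 and 0.0536 TPM in any heterozygous pool. cbln5 and cbln9, of the cerebellin family of secreted proteins, stood at 34.9 ± 7.67 and 19.96 ± 4.92 TPM in the wild type and at 0.0582 ± 0.0595 and 0.516 ± 0.662 TPM in the heterozygotes.

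In all, 227 of 16537 genes passed the threshold in limma, 134 higher and 93 lower in the heterozygotes. At an unadjusted limma p under 0.05 there were 2481, and in 21.7% of the tested genes the groups did not overlap. Random labels give 10% on average, but genes vary together, and the share in other splits was not computed. Of the called genes 101 had a gene-like symbol, 57 higher and 44 lower. Under quantile normalization the split was 183 higher and 77 lower. The count moved with single libraries: it was 849 without wild-type pool 1, 47 without pool 2 and 4 without pool 3, and 38, 41 and 20 without heterozygous pools 1, 2 and 3. Part of the loss was set by the filter, which still asked for 3 libraries and so dropped genes present in the reduced genotype alone. Of the 227 called genes, 170 were still tested without any 1 wild-type pool and 156 without any 1 heterozygous pool. Without wild-type pools 2 and 3 together, 159 were. Without wild-type pools 2 and 3, which held the egg transcripts, limma called 0 genes, with 2087 at an unadjusted p under 0.05 and 1 wild-type library left.

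**Figure D2:**
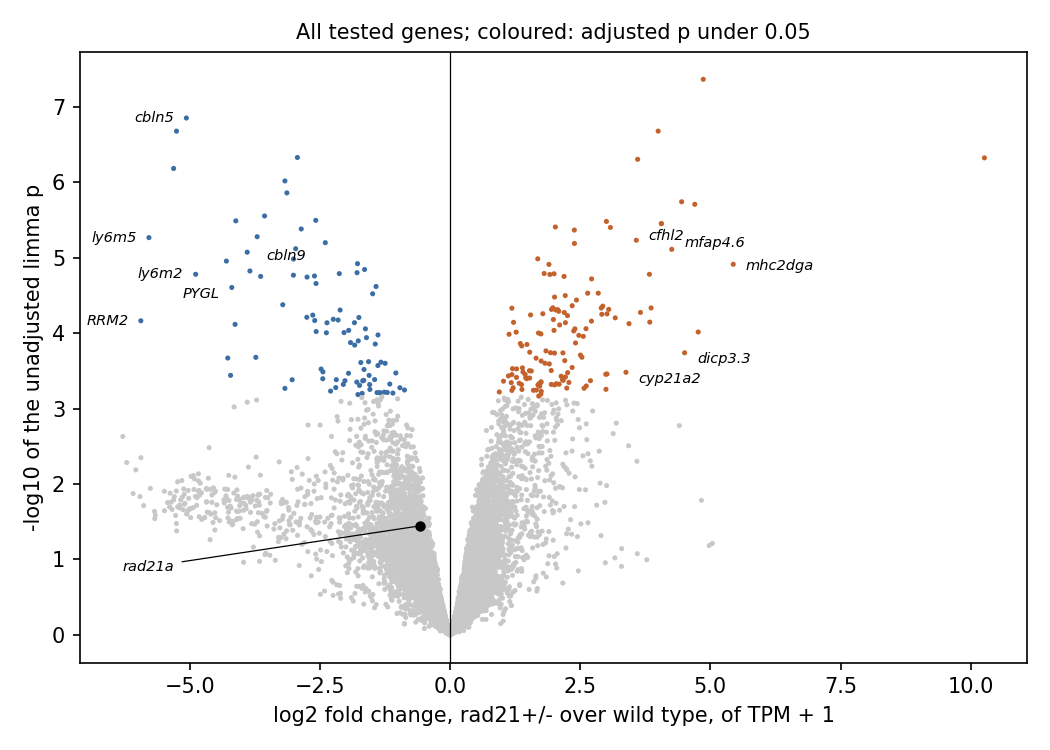
Log2 fold change of TPM + 1, heterozygous over wild type, against -log10 of the unadjusted limma p for all 16537 tested genes. Coloured points are the 134 higher and 93 lower genes past the adjusted threshold, named genes are in italics, and the black point is rad21a, which did not pass.

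Among the other named genes that rose, MFAP4 (ENSDARG00000038681) went from 1.47 ± 0.544 to 64.2 ± 19.3 TPM, with a log2 fold change of 4.70 ± 0.32 (SE, limma adjusted p = 0.0027). MFAP4 (ENSDARG00000089667) went from 0.309 ± 0.340 to 43.5 ± 39.5 TPM. The summed TPM of all 8 genes with the symbol MFAP4 was 314 ± 71.1 in the wild type and 274 ± 120 in the heterozygotes, so the groups overlapped for that symbol, a sum that leaves out mfap4.6 and the other family members with a symbol of their own. dicp3.3, of a family of immunoglobulin-domain receptors, went from 1.55 ± 1.05 to 69.3 ± 61.6 TPM, and cfhl2, named as a relative of complement factor H, from 0.173 ± 0.104 to 13.5 ± 4.98 TPM. RFESD (ENSDARG00000058725) went from 0.341 ± 0.168 to 17.8 ± 11.4 TPM, and the summed TPM of both genes with that symbol from 4.11 ± 0.698 to 22.1 ± 11.4. cyp21a2, the steroid 21-hydroxylase, went from 0.656 ± 0.330 to 18.7 ± 11.3 TPM, with 6.58 TPM in heterozygous pool 1 and 20.6 and 29.0 TPM in the pools that held interrenal transcripts. ENSDARG00000102208, which has no gene-like symbol, stood at 3879, 1850 and 1108 TPM in the heterozygous pools and at no more than 1.88 TPM in any wild-type pool. ENSDARG00000094712 was listed at 0 in all 3 wild-type pools and at 13.2, 17.7 and 14.3 TPM in the heterozygous pools.

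Among the other named genes that fell, RRM2 (ENSDARG00000020711), the small subunit of ribonucleotide reductase, had the most negative log2 fold change of the rule, -5.94 ± 0.69 (SE, limma adjusted p = 0.013). It stood at 70.8, 424.8 and 112 TPM in the wild-type pools and at 1.98, 2.52 and 0.429 TPM in the heterozygous pools. The sum of both genes with the symbol RRM2 was 398 ± 369 TPM in the wild type and 193 ± 27.1 TPM in the heterozygotes, which overlapped. PYGL, a glycogen phosphorylase, went from 29.3 ± 16.8 to 0.555 ± 0.449 TPM. SNORA63 (ENSDARG00000083378), a small nucleolar RNA, went from 51.9 ± 12.6 to 2.28 ± 1.98 TPM, and the sum over its 3 genes from 59.5 ± 18.7 to 5.96 ± 3.05 TPM. Genes named 5S_rRNA, of which 130 were tested, were called in both directions, 11 higher and 7 lower, and 8 of the named genes were among them. Their summed TPM over all 1901 listed copies was 904 ± 165 in the wild type and 1120 ± 126 in the heterozygotes, a difference within the range of the libraries. With 1 library left out, the called named genes that were still tested kept their direction, as genes without overlap between the groups must. Of these 26, 19 were tested and 19 called without wild-type pool 1, 12 of 19 without pool 2 and 3 of 19 without pool 3, and 13, 13 and 9 of 18 without heterozygous pools 1, 2 and 3.

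**Figure D3:**
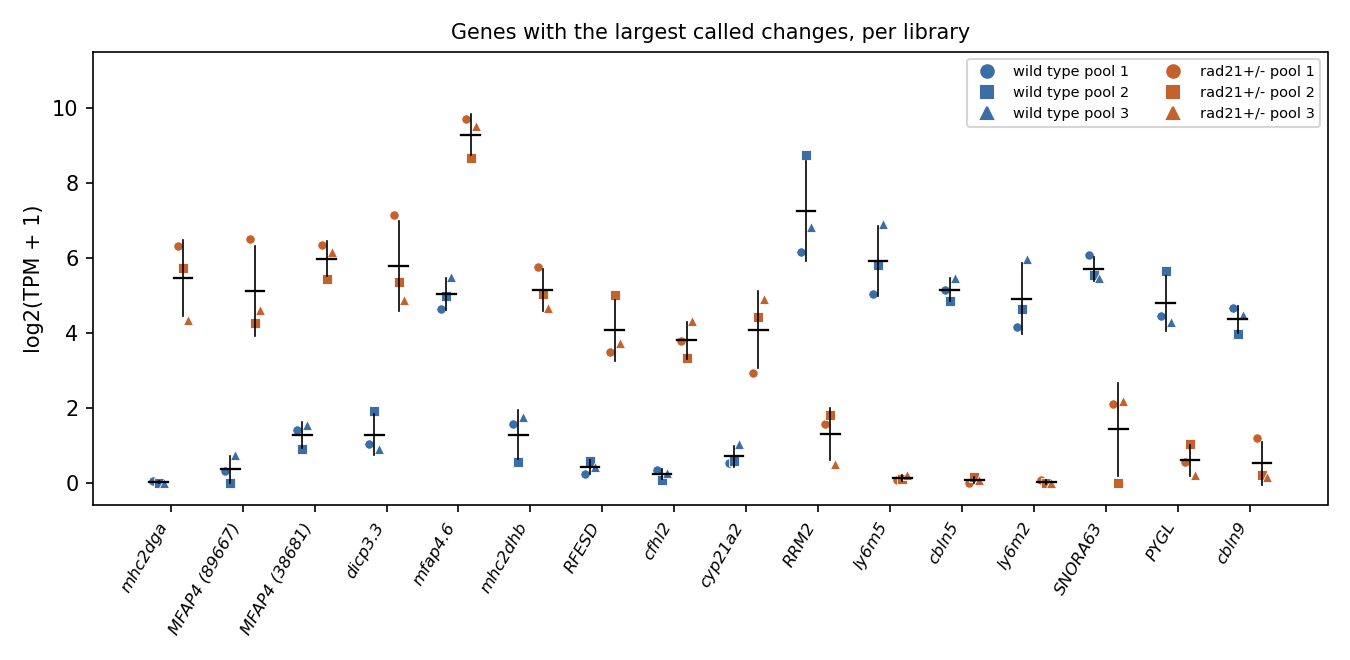
Levels of the named genes with the largest called changes as log2(TPM + 1), 1 point per library, with the mean and SD of 3 pools as bars, without the 5S_rRNA genes and with the last identifier digits telling the MFAP4 genes apart. The heterozygous pools of mhc2dga (19.3 to 78.1 TPM) and the wild-type pools of ly6m5 (31.8 to 117.6 TPM) face values near 0 in the other genotype.

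Gene lists showed which groups moved together, and 12 of the 34 tested were called by limma's camera with the preset correlation, 8 higher and 4 lower in the heterozygotes. With an estimated correlation 0 of the 34 were called, with 1 list, skeletal muscle, at an unadjusted p under 0.05. With fry 1 list was called, skeletal muscle (adjusted p = 0.029). With its members matched without copy suffixes, 12 of them tested, fry did not call that list (adjusted p = 0.065).

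Ribosomal protein genes were higher as a list: 80 of 83 had a positive fold change, with a mean of 0.30 on the log2 scale (limma camera adjusted p = 2.5e-12, adjusted p = 0.91 with an estimated correlation). None passed alone over all genes or adjusted over the list alone. RPLP1, of the ribosomal stalk, stood at 3201, 2638 and 3436 TPM in the wild type and 5046, 4459 and 4201 TPM in the heterozygotes. In the proteasome list 38 of 45 members were positive, with a mean of 0.35 (limma camera adjusted p = 1.5e-06, adjusted p = 0.91 with an estimated correlation). PSMB9, a catalytic subunit of the immunoproteasome that trims peptides for MHC class I, was its 1 member called over all genes and adjusted over the list alone, and rose from 15.0 ± 3.87 to 72.8 ± 13.7 TPM (limma adjusted p = 0.013). Its members psma6l, psmb13a and psmb12 had log2 fold changes of 1.06, 0.96 and 0.83. Without wild-type pool 1 the proteasome mean was 0.22. Oxidative phosphorylation genes had 65 of 83 positive and a mean of 0.17 (limma camera adjusted p = 0.0032, adjusted p = 0.95 with an estimated correlation), with 0 called alone by either adjustment. cox6b1, a subunit of cytochrome c oxidase, had the smallest p, with a log2 fold change of 1.17. That list's call was lost without wild-type pool 1 (mean 0.024, limma camera adjusted p = 0.17) and without heterozygous pool 3 (mean 0.060, limma camera adjusted p = 0.14), and its mean was 0.27 without heterozygous pool 1.

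Of the immune lists, those of B cell and immunoglobulin genes and of interferon response genes were higher. In the B cell and immunoglobulin list 17 of 20 members were positive, with a mean of 0.90 (limma camera adjusted p = 2.5e-05, adjusted p = 0.91 with an estimated correlation). None passed over all genes and 5 did adjusted over the list alone, each at a limma adjusted p of 0.045: cd37, igic1s1, irf4b, ighm and cd79a. With members matched without copy suffixes 26 were tested, and 0 passed adjusted over the list alone. Light-chain gene igic1s1 stood at 14.7, 31.4 and 51.4 TPM in the wild type and 457.4, 97.8 and 157.7 TPM in the heterozygotes, and ighm, the IgM heavy chain, at 40.2, 40.1 and 116.5 TPM and 540.6, 153.9 and 185 TPM. Heterozygous pool 1 was the highest library for both, and without it the list's mean was 0.57. Interferon response genes had 28 of 30 positive, with a mean of 0.69 (limma camera adjusted p = 8.1e-06, adjusted p = 0.91 with an estimated correlation) and 0 called alone by either adjustment. Its members of smallest p were the feedback inhibitors socs1b and usp18, the transcription factor IRF7, and ifi35, with log2 fold changes of 0.74, 1.12, 1.004 and 0.79. With the germ cell score as a covariate the interferon mean was 0.59 and the call was lost (limma camera adjusted p = 0.059), and without wild-type pools 2 and 3 the mean was 0.80 and the list was called (limma camera adjusted p = 0.0052).

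The macrophage and neutrophil lists were called by a smaller margin. Of 30 macrophage genes 19 were positive, with a mean of 0.40 and a median of 0.12 (limma camera adjusted p = 0.034, adjusted p = 0.95 with an estimated correlation). Both MFAP4 genes above were called over all genes, and adjusted over the list alone a further MFAP4 gene was also past the threshold in the other direction, at 134, 96.8 and 194.6 TPM in the wild type and 48.5, 59.4 and 64.8 TPM in the heterozygotes. LGMN, a lysosomal protease, had a log2 fold change of 0.90. Neutrophil granule and effector genes had 22 of 27 positive and a mean of 0.32 (limma camera adjusted p = 0.034, adjusted p = 0.95 with an estimated correlation), with 0 called alone by either adjustment. Among its members of smallest p, adam8a and ALOX5AP had log2 fold changes of 1.09 and 1.12, and were highest in heterozygous pool 1. Without that pool the neutrophil mean was -0.02 and the macrophage mean 0.13, both no longer called (limma camera adjusted p = 0.69 for each). Neutrophil genes were also not called without wild-type pool 1 or 2 (limma camera adjusted p = 0.076 and 0.21), nor macrophage genes without wild-type pool 2 (limma camera adjusted p = 0.15). Without wild-type pools 2 and 3 together, with 1 wild-type library left, the means were 0.57 for neutrophil and 0.60 for macrophage genes, and neither list was called (limma camera adjusted p = 0.22 and 0.48). Under quantile normalization neither was called at means of 0.37 and 0.46 (limma camera adjusted p = 0.14 for each). The macrophage call was also lost with camera on ranks, which leaves the mean as it is, with members matched without copy suffixes (mean 0.30) and with the germ cell score (mean 0.50), at limma camera adjusted p = 0.10, 0.10 and 0.27. Without wild-type pool 3 the macrophage mean was 0.62 and the neutrophil mean 0.52, and the neutrophil mean was 0.20 without wild-type pool 1 and 0.50 and 0.48 without heterozygous pools 2 and 3. Interrenal and chromaffin genes had 7 of 7 positive and a mean of 2.01 (limma camera adjusted p = 0.0074, adjusted p = 0.91 with an estimated correlation), with cyp21a2 called over all genes and adjusted over the list alone. STAR, which brings cholesterol into mitochondria for steroid synthesis, stood at 0.0897, 374.8 and 560.7 TPM in the heterozygous pools and at no more than 1.33 TPM in the wild type. Without heterozygous pool 3 the interrenal mean was 1.26, and without pool 1 it was 3.101. Without wild-type pools 2 and 3, with 1 wild-type library left, the interrenal mean was 2.04. The interrenal call was lost with the germ cell score as a covariate, at a mean of 1.41 (limma camera adjusted p = 0.40). That score includes STAR, which the interrenal list also holds, so the fit cannot show whether germ cell RNA bears on this list.

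Among the lower lists, that of cell division genes had the smallest p by camera at the preset correlation. Mean falls were larger for gonad and skeletal muscle genes (-3.39 and -1.94). In the G2 and mitosis list 39 of 42 members were negative, with a mean of -0.98 (limma camera adjusted p = 5.3e-11, adjusted p = 0.91 with an estimated correlation), and 0 were called alone by either adjustment. ECT2, needed for cytokinesis, stood at 5.32, 10.97 and 6.46 TPM in the wild type and 1.97, 3.36 and 2.53 TPM in the heterozygotes. The mitotic kinase aurka stood at 14.2, 114 and 42.4 TPM and at 6.97, 7.92 and 6.43 TPM, highest in the wild-type pools that held egg transcripts. In the gonad list 12 of 13 members were negative, with a mean of -3.39 (limma camera adjusted p = 6.0e-05, adjusted p = 0.91 with an estimated correlation), with 0 called over all genes and 10 adjusted over the list alone. Its 1 positive member was STAR, which the interrenal list also holds. Without wild-type pools 2 and 3, with 1 wild-type library left, the gonad mean was -1.03 (limma camera adjusted p = 0.00055). Egg coat gene zp2.3 stood at 42.7, 2660 and 754.6 TPM in the wild-type pools and at 23.7, 14.8 and 0.426 TPM in the heterozygous pools. DNA damage repair genes had 37 of 48 negative and a mean of -0.32 (limma camera adjusted p = 0.045, adjusted p = 0.95 with an estimated correlation), with 0 called alone by either adjustment, and RAD51C and FANCF, of recombination and crosslink repair, were highest in wild-type pool 2. That call was lost without wild-type pool 2 (mean -0.04, limma camera adjusted p = 0.90) and without heterozygous pool 3 (limma camera adjusted p = 0.27). Without wild-type pool 1 its mean was -0.60. The mean turned to 0.26 without wild-type pools 2 and 3 (limma camera adjusted p = 0.10), and with the germ cell score as a covariate the list was called in the other direction (mean 0.41, limma camera adjusted p = 0.00064). The mean of the mitotic list was -0.65 without wild-type pool 2, where the list was still called at the preset correlation (limma camera adjusted p = 3.2e-11). Without pools 2 and 3 it was -0.44, against 1 wild-type library, which cannot show whether a difference stays. With the germ cell score as a covariate the list was still called (mean -0.19, limma camera adjusted p = 0.0028).

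Skeletal muscle genes fell as a list: 8 of 8 members were negative, with a mean of -1.94 (limma camera adjusted p = 1.8e-08, adjusted p = 0.58 with an estimated correlation). Over all genes 3 were called, and 8 adjusted over the list alone. Calcium-binding parvalbumins pvalb1 and pvalb2 went from 25.3 ± 4.59 to 3.44 ± 1.33 TPM and from 11.01 ± 3.78 to 0.887 ± 0.355 TPM, and the sarcomeric actin gene actc1b from 13.7 ± 2.44 to 2.34 ± 0.719 TPM (limma adjusted p = 0.013, 0.012 and 0.013). The muscle list was called with each library left out in turn. Over all alternatives its mean ran from -2.44, without wild-type pools 2 and 3 and with 1 wild-type library left, to -1.21. Its members atp2a1 and the myosin heavy chain genes myhz1.1 and myhz2 were too low to test, at no more than 1.24, 0.0495 and 0.0707 TPM in any library.

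**Figure D4:**
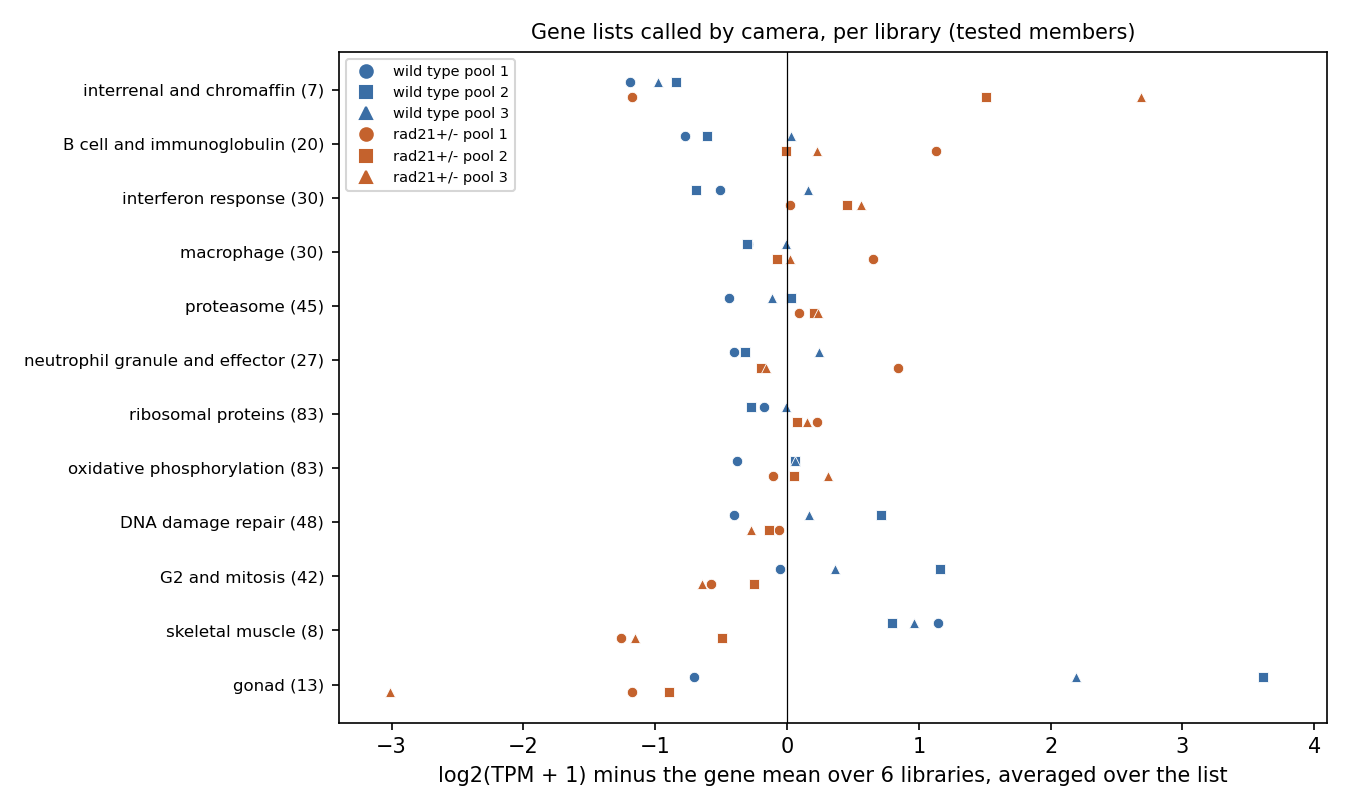
Mean deviation of log2(TPM + 1) from each gene's mean over the 6 libraries, averaged over the members of each called list, with 1 point per library and the number of tested members in brackets. Wild-type pools 2 and 3 reach 3.61 and 2.19 for the gonad list, and heterozygous pools 2 and 3 reach 1.51 and 2.68 for the interrenal list.

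Blood stem and red cell groups were among the 22 lists not called. Of 12 tested stem and progenitor regulators 9 were positive (mean 0.15, limma camera adjusted p = 0.31). MYB, needed for definitive blood formation, stood at 36.5, 34.04 and 44.7 TPM in the wild type and 82.9, 67.4 and 59.9 TPM in the heterozygotes. Its log2 fold change was 0.85, and it did not pass over all genes (limma adjusted p = 0.17) or adjusted over the list alone (limma adjusted p = 0.081). Erythroid regulators and membrane genes had 13 of 20 positive and a mean of 0.13 (limma camera adjusted p = 0.38), and haem synthesis genes 11 of 16 positive and a mean of 0.04 (limma camera adjusted p = 0.65). The alpha globin hbaa1 ranged from 10550 to 38220 TPM in the wild type and from 11040 to 23830 TPM in the heterozygotes. Thrombocyte, T cell, granulocyte and monocyte regulator, kidney tubule and endothelial genes were not called either, with limma camera adjusted p between 0.18 and 0.90. S phase genes had 30 of 44 negative and a mean of -0.43 (limma camera adjusted p = 0.20), with RRM2 (ENSDARG00000020711) the 1 member called over all genes and adjusted over the list alone. Regulators that load and release cohesin, with CTCF, had 11 of 13 negative and a mean of -0.29 (limma camera adjusted p = 0.19). The sign of the test and of the mean differed for ribosome biogenesis (mean -0.01) and polycomb and DNA methylation genes (mean -0.11), both tested as higher and not called, and the mean and median differed in sign for T cell and for NK and cytotoxic genes.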

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

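Chosen after seeing the data were the fits without wild-type pools 2 and 3 or with the germ cell score, and list matching without copy suffixes. The count of called genes (227, 134 higher and 93 lower) stayed within 1.5 times under both other pseudocounts, median ratio scaling, quantile normalization, removal of globin and mitochondrial genes, no variance trend and a fold change of at least 1.5. It fell to 132 (75 higher, 57 lower) with no filter and 117 (71 and 46) at a TPM of at least 5, where 118 of the 227 called genes were still tested, and rose to 397 (243 and 154) at an adjusted p under 0.1. Library weights gave 7397 (2088 and 5309), but that fit did not converge and put a weight of 106 on wild-type pool 3 against 0.143 to 1.45 on the others, and rad21a then passed (-0.78). With the germ cell score as a covariate 53 were called (16 and 37), and without wild-type pools 2 and 3 limma called 0 (0 and 0). Leaving out 1 library gave 4 to 849 genes, 4 to 183 higher and 0 to 666 lower. The cause of these moves was not tested. Leaving out a library also leaves fewer samples, and only 156 or 170 of the 227 called genes were then still tested. The median log2 fold change of all genes, -0.02, moved to 0.17 without wild-type pools 2 and 3, 0.14 with the germ cell score and -0.16 with library weights. No called gene that was still tested turned direction in any of these fits. For genes without overlap between the groups, leaving out libraries cannot turn the direction.

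Samples with the same replicate number did not deviate together (correlations -0.27, 0.12 and -0.13 for numbers 1 to 3). Samples with different numbers gave -0.33 to 0.37. Egg and interrenal RNA differed between the pools and could hide a pairing, so whether the numbers pair the samples cannot be told. With replicate number as a block 25 genes were called (10 and 15), and the block spends degrees of freedom.

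The log2 fold change of rad21a stayed negative, between -0.87 with the germ cell score and -0.49 without wild-type pool 1, and limma called it with library weights alone. The 12 called lists (8 higher, 4 lower) became 0 (0 and 0) with an estimated correlation and 1 (0 and 1) with fry. Without wild-type pools 2 and 3 there were 19, 12 of them lower, and with the germ cell score 10 lower lists. Leaving out 1 library gave 10 to 18 lists, 7 to 11 higher and 3 to 7 lower. For each of these the cause was not tested.

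Over the called lists and all alternatives, 210 values stayed called in the same direction, 49 lost the call and 4 turned: neutrophil genes with library weights (-0.29) and without heterozygous pool 1 (-0.018, against at most 0.52 without another library), and DNA damage repair without wild-type pools 2 and 3 (0.26) and, called higher, with the germ cell score (0.41, limma camera adjusted p = 0.00064). DNA damage repair also lost its call with a pseudocount of 0.1, with either other filter, under quantile normalization, with library weights and with members matched without copy suffixes, at limma camera adjusted p between 0.052 and 0.15. Library weights ended the macrophage call too (limma camera adjusted p = 0.38). Over the named genes 437 were the same, 88 lost the call and 1, a STAG1 gene, gained it. The 11 that turned were cohesin genes that were never called: STAG2 (ENSDARG00000011783) with library weights (-0.047), without wild-type pool 2 (-0.0042, against at most 0.27 without another library) and with the germ cell score (-0.070); SMC3 without wild-type pools 2 and 3 (-0.064) and with the germ cell score (-0.056); SMC1A with library weights (-0.019); and RAD21 with library weights (-0.070), without wild-type pool 2 (-0.13, against at most 0.17 without another library), without heterozygous pool 1 (-0.04), without wild-type pools 2 and 3 (-0.23) and with the germ cell score (-0.30).

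The planned count test was not run, because whole reads were not recovered, and neither was the chromosome test with its alternatives, because positions on the build of the files were not used here. Read depth is unknown, so how far low genes are limited by counting error cannot be given.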

Other observations

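The requirement that groups be apart in the test of shared copies, the matching by level, and the tests of inherited copies, the linked chromosome stretch, germ cell RNA, wild-type pool 1 in the mitotic list and muscle were chosen after the values they measure were seen. These families and genes were chosen after their values were seen, and enrichment was not tested. Of the MHC class II genes whose symbols start with mhc2, 3 of 6 tested were called higher, with mhc2dgb going from 0.302 ± 0.0586 to 10.8 ± 6.58 TPM (SD, n = 3 each). Among interferon-induced families, 3 of 8 ifi44 genes, 2 of 9 gig2 genes and 2 of 43 ftr genes were called higher. Of the ighv immunoglobulin genes, 1 of 27 was called higher. A further gene, tapbp.1, named after the MHC class I loading factor tapasin, went from 0.790 ± 0.319 to 14.1 ± 2.34 TPM. Both tested gsta genes, glutathione transferases, were called higher, and gsta.1 went from 22.9 ± 3.78 to 61.7 ± 5.80 TPM. Myoglobin (mb) went from 235 ± 44.9 to 694 ± 135 TPM, against the direction of the muscle list. The troponin gene TNNI2 and the microRNA gene dre-mir-133c, by contrast, were called lower, with log2 fold changes of -1.68 and -2.93. Of 6 tested cbln genes 4 were called lower.

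Within the NK and cytotoxic list, which was not called as a whole (limma camera adjusted p = 0.88), members went both ways. Adjusted over the list alone, 2 rose and 2 fell, and 0 were called over all genes. Granzyme genes gzma and gzmk had log2 fold changes of 1.36 and 0.91, and nkl.4 and ccl38.6 had -1.48 and -1.44. In the p53 target list sesn2, a stress-induced gene, had a log2 fold change of -1.40 and was the 1 member past the threshold adjusted over the list alone (limma adjusted p = 0.053 over all genes).

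The 227 called genes compare with at most 0 in the other 9 splits of the libraries into 3 and 3, and 1 of the 10 splits, the real one, gave as many, which is too few splits for a share under 0.05. Of the 88 called genes that could be placed by symbol on assembly GRCz12tu, 4.55% lay on the chromosome of rad21a, against 4.81% of the placed tested genes, which argues against a linked stretch of chromosome for these 88 genes. The check is void for the 227 called genes as a set, because 38.8% were placed.

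A first pattern was a set of 61 genes at a TPM of at least 1 in every library of a genotype and under 0.1 in every library of the other, 37 of them present in the heterozygotes and 24 in the wild type. Other splits gave at most 12, and 1 of the 10 splits gave as many, again too few for a share under 0.05. The stretch of chromosome linked to rad21a was not tested on these genes, 51 of which have a shared or no gene-like symbol. Of the 61, 83.6% had a shared or no gene-like symbol, 1.64 times the share of other genes of the same mean level. Copies or alleles that differ between the pools elsewhere in the genome may contribute. Reads shared between copies would raise that share too, so it cannot tell the 2 explanations apart. Reads shared between copies stay open, as does the genotype: the summed TPM moved by at least 0.5 on the log2 scale in 60% of the 5 shared symbols, over the bound set in advance against this explanation, but in 40% with the groups also apart, and 20 of the 24 genes these symbols cover are 5S_rRNA, whose sum moved by 0.32 with the groups overlapping.

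A second pattern was the lower mitotic list. Germ cell RNA in wild-type pools 2 and 3 may account for much of it: with the germ cell score of 13 gonad genes as a covariate, which left the list called (limma camera adjusted p = 0.0028), the median log2 fold change of the 42 mitotic genes went from -0.80 to -0.27, and the list mean from -0.98 ± 0.38 to -0.19 ± 0.31 (SE), or to -0.19 ± 0.38 with STAR left out of the score. Growing oocytes hold stored cell-cycle transcripts, and buc, an oocyte gene of the gonad list, stood at 285.4 and 105.2 TPM in those pools. Wild-type pool 1 lay above the highest heterozygous library by 0.20 in the mitotic score, and 1 library cannot decide whether a smaller difference stays. An effect of genotype on cycling marrow cells stays open and untested, since the germ cell score was itself lower in each heterozygous pool than in each wild-type pool.

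A further pattern was the lower muscle list. Muscle carried over with the wild-type marrow may account for it: the 6 muscle genes most abundant here all had lower levels, by similar amounts, with a median log2 fold change of -2.11 and an SD over genes of 0.40. The list summed to 124.4, 88.6 and 102.1 TPM in the wild type and 13.6, 29.8 and 14.3 TPM in the heterozygotes. Those genes were picked by their level here, however, and 6 of the 14 members in the table, among them the muscle-abundant atp2a1 and myhz2, stayed too low to test, at no more than 1.24 and 0.0707 TPM, which muscle tissue would not predict unless reads were lost between copies. Carried-over muscle and an effect of genotype cannot be told apart for this reason.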
